A study of Oryza sativa with 3 samples.

How the data were processed

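Gene expression was measured in total RNA of rice roots on 3 arrays of 2 channels each, with As(V)-treated RNA labelled with Cy5 and water-treated RNA with Cy3, per the labels' protocols. RNA was amplified linearly and labelled during transcription in vitro, per the labels' protocols. The labels describe 3 biological replicates and give each array's replicate number. All 3 arrays formed 1 group, with each array setting 1 treated sample directly against 1 water sample. The 2 samples of an array share that array, so no further pairing of samples was used.

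The deposited scanner files hold, per spot and channel, the mean intensity and the median local background intensity on a linear scale, not normalized, per the file headers. They were written by Agilent Feature Extraction 9.5.3.1 for arrays 1 and 2 and 10.5.1.1 for array 3, per the file headers. The same files hold processed intensities, which the scanner software had detrended, background-adjusted and dye-normalized, and their log10 ratio of red over green, per the file headers. The flags for spots above background, saturated spots and outliers are 0 or 1 in the deposited files. The deposited series table holds log2 ratios that lay within 0.001 of the scanner software's log10 ratio turned to base 2 for most probes, which set their direction as As(V) over water and showed that they were not centred further. How the authors made that table is not given in the sources used here. Slides, scans and scanners were taken from the file headers as numbers. Arrays 1 and 2 shared all 3, and array 3 differed in all 3. The scanner software's own figures for the spike-in RNAs gave a slope of observed on expected log ratio of 0.842, 0.851 and 0.844 on arrays 1, 2 and 3.

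The mean intensities were background-corrected with normexp and an offset of 50 and normalized within each array by loess, in which control and outlier spots had weight 0. No scaling was applied between arrays. Control spots and spots with outlier flags were then left out, saturated spots were kept, and spots of one probe were averaged. Of 42418 probes for rice loci or microRNAs, 36895 were well above background in at least 1 channel on at least 2 arrays and were tested. A further 590 spots that name no rice gene were left out. limma 3.58.1 in R 4.3.3 fitted the mean log2 ratio of As(V) over water per probe, with eBayes moderation (2.02 prior degrees of freedom beside 2 residual ones), a two-sided test against 0 and Benjamini-Hochberg adjustment over all probes. A positive log2 ratio means higher under As(V). For the 1 probe per gene, the brightest over the 3 arrays was taken, which gave 25818 genes, 7111 loci having several tested probes. Counts of genes include microRNAs, for which 219 probes were tested. None of the genes named had another probe past the threshold in the other direction. Log2 ratios understate the change of dim genes because of the offset.

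Before the data were examined, 38 gene lists, the tests, the processing alternatives and a rule for naming genes were fixed. Lists were patterns on the descriptions in the scanner files or, for arsenic, phosphate and iron genes, locus identifiers. The symbols of those loci, such as PCS1 or NAS1, are the names under which the loci entered the lists and do not come from the files. Lists were tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the 38 lists, with an estimated correlation and fry beside it. With 3 arrays the estimated correlation rests on 2 residual degrees of freedom. The rule named the 8 genes with the highest and the 8 with the lowest log2 ratio among those past the threshold with 1 sign on all arrays and a description that names a protein, the 2 members of each list with the largest change, and all members of the arsenic, phosphate and iron lists. That gave 109 genes. Names and descriptions are those of the array's design and can be old. The digits after Os in an identifier give the chromosome. Genome coordinates were not used here, and the reference table given with the files held no match to these identifiers.

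For a probe not well above background on any array in 1 channel, the fitted log2 ratio depends on the offset and is given without a bound.

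The loess, limma and camera steps were tested on simulated data with the real intensities and spreads. An intensity-dependent dye curve was added, and 200 probes among 36860 were changed. Background correction, outlier weights, the filter on dim probes and the averaging of spots were not part of the simulation. Loess reduced the curve's SD from 0.453 to 0.0257. Of 50 probes changed by each log2 size, 0 were called at 0.5, 8 at 1, 25 at 2 and 35 at 3, all with the right sign, and 3 unchanged probes were called. A list of 60 probes, most of them shifted upward by 0.5, had a camera p of 1.84e-24 and an unshifted one 0.514. The noise of each probe on each array was drawn independently. The simulated lists thus lacked the correlation between genes that real lists can have, and the simulated arrays lacked any error shared by a slide. With only 200 changed probes, the simulation does not show how loess behaves where 33.9% of probes pass, as in the data.

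Alternatives covered no background subtraction, an offset of 16, the scanner software's processed intensities, median centring, scale and Aquantile normalization, no filter and a stricter filter on dim probes, leaving out saturated probes, a trended and robust variance model, each array left out in turn, the series table, the slide as a block, a test against a 1.5-fold change, a separate-channel model, an estimated set correlation and the mean of all probes of a gene. A random slide block and the heat shock list without small heat shock proteins were added after seeing the data.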

Results

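Roots of 5-day-old rice seedlings of the cultivar TN-67 were exposed to 25 µM arsenate, written As(V) here, the oxidised and phosphate-like form of inorganic arsenic. Control roots received water. Each of 3 oligonucleotide arrays held the labelled RNA of 1 treated sample, in Cy5, together with that of 1 water sample, in Cy3, and the labels name the 3 arrays as biological replicates. The dyes were never exchanged, so the treatment and the dye could not be told apart on any single probe. Arrays 1 and 2 lay on 1 slide and array 3 on another. In the As(V) channel 85.1%, 84.5% and 90.4% of the probes for rice loci or microRNAs were well above background on arrays 1, 2 and 3, and in the water channel 82.7%, 82.8% and 89.1%. A probe above background need not show specific signal, since 48.3% of the spots of random control probes were so in the As(V) channel. The number of arrays, 3, limits the precision of every value. How long the roots were exposed is not given in the sources used here.

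The comparison asks which transcripts differ between As(V)-treated and water-treated roots. The transcripts that rose included those of 19 of 35 small heat shock proteins, 18 of 38 jasmonate genes, 29 of 65 glutathione transferases and 31 of 64 WRKY factors. Those that fell included 10 of 12 genes of the iron deficiency response, the silicic acid transporters Lsi1 and Lsi2, 48 of 187 cell wall proteins, 35 of 118 class III peroxidases and 36 of 114 cell division genes. In camera with a preset correlation the lists of these genes passed, except the arsenic list that holds Lsi1 and Lsi2 (adjusted p 0.85). Small heat shock proteins were tested only within a list of 174, whose adjusted p without them was 0.143. With an estimated correlation the adjusted p of each list was 0.984. The WRKY list lost its call without array 3 as well, with an adjusted p of 0.0674. The division list lost its call with median centring and the cell wall list with no filter on dim probes. The peroxidase list lost its call without array 1, with median centring, with no filter or a stricter one, and with the deposited log2 ratios. Of 36895 probes tested with limma, 7302 were higher and 5203 lower under As(V), at a Benjamini-Hochberg adjusted p under 0.05. At least 2-fold differences were found for 3381 probes higher and 1787 lower. With 1 probe per gene, 5136 of 25818 genes, microRNAs included, rose and 3699 fell, of which 460 rose and 58 fell at least 8-fold. Of the probes past the threshold, 7298 higher and 5200 lower ones had a value on all 3 arrays, and all of these had 1 sign throughout. With 3 arrays the threshold leaves almost no room for mixed signs, so this shows no agreement beyond the test itself. The same holds for signs kept when 1 array is left out. Higher probes made up 58.4% of those past the threshold, and 45.9% with the authors' deposited log2 ratios, which were not centred.

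The count depended on single arrays. Over 36872 probes, arrays 1 and 3 correlated at r = 0.858, arrays 2 and 3 at 0.764 over 36868, and arrays 1 and 2, which shared a slide, at 0.952 over 36875. These are correlations across probes, which are not independent replicates. Without array 1 the fit passed 1630 probes higher and 147 lower, without array 2 it passed 4238 and 1459, and without array 3, within slide 1, it passed 9755 and 9492. With the slide as a block it passed 10076 higher and 8856 lower. That fit takes its residual spread from arrays 1 and 2 alone, so its larger counts do not show that array 3 matched them. Array 3 was the only array of its slide and gave no test of its own.

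**Figure D1:**
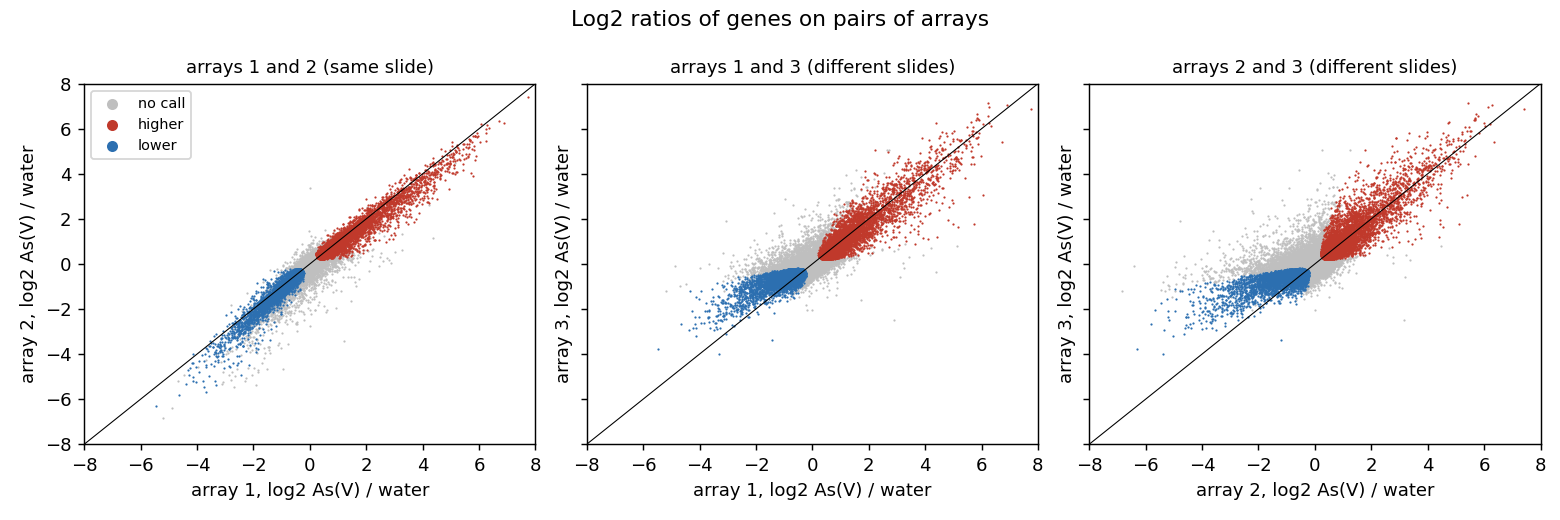
Each panel sets the log2 ratio of As(V) over water of every tested gene on 1 array (x axis) against another array (y axis), with genes that passed the threshold upward in red, downward in blue and the others in grey, and the line of equal values in black. Genes on arrays 1 and 2 lie near the line, below it for many of those with large changes, while on array 3 the points of genes that were lower lie above it, with 5 genes at least 8-fold lower on array 3 against 99 on array 1 and 273 on array 2.

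The 8 genes with the strongest rises among those whose description names a protein included 4 of the heat shock class. The small class II heat shock protein Os01g0184100 had a log2 ratio of 7.34 ± 0.45 (SD, n = 3), a value limited by saturation of its As(V) signal on 2 arrays. Heat shock protein 70 Os03g0277300 reached 6.73 ± 0.41, HSP81-1, Os04g0107900, 6.47 ± 0.45 on its brightest of 5 probes, and heat shock protein 26 Os03g0245800 6.0 ± 0.39. An oxophytodienoic acid reductase, Os06g0215500, rose by 6.20 ± 0.39 and the ethylene-responsive transcriptional coactivator Os06g0592500 by 6.15 ± 0.67. A carboxyl methyltransferase, Os02g0719600, rose by 6.07 ± 0.51 and the RING finger protein Os07g0631200 by 5.99 ± 0.41. The strongest falls were those of a dormancy/auxin associated protein, Os09g0437500, at -5.17 ± 1.30, the probenazole-inducible protein PBZ1, Os12g0555500, at -4.24 ± 1.05, and the Myb domain protein Os11g0700500 at -4.22 ± 1.22. A protein kinase, Os02g0228300, followed at -3.90 ± 1.45, beta-expansin Os03g0102700 at -3.89 ± 0.94, and the ABC transporter Os03g0281900 at -3.80 ± 1.82. The remaining pair were the Avr9/Cf-9 rapidly elicited protein Os03g0179400 at -3.77 ± 1.51 and the beta glucanase Os05g0375400 at -3.70 ± 1.56. Adjusted p in the limma fit ran from 0.000961 to 0.0015 for the 8 rises and from 0.0068 to 0.029 for the 8 falls. Without array 1, 7 of the 8 falls and 0 of the 8 rises lost their call in limma, as did 44 of all 98 named genes that passed. Without array 2, 10 of the 98 lost it, and all kept their sign.

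Of 174 heat shock proteins and chaperones tested, proteins that keep others folded, 56 rose and 17 fell (62 and 19 adjusted over the list alone), with 40 rising and 4 falling at least 2-fold. Of the 35 small heat shock proteins 19 rose and 3 fell, 17 of the rises being at least 8-fold, with a median log2 ratio of 2.14. Of the other 139 members 37 rose and 14 fell, 11 of the rises being at least 8-fold, with a median of 0.09. Heat shock transcription factors, a family of regulators of heat shock genes, counted 11 higher and 0 lower of 23 (11 and 4 over the list alone), among them Spl7, Os04g0568700, at 4.2 ± 0.23 and RHSF2, Os08g0546800, at 4.08 ± 0.14. In camera with the preset correlation the adjusted p was 0.0197 for the proteins and 0.0437 for the factors, and with an estimated correlation the adjusted p was 0.984 for both. List medians were 0.20 on slide 1 and 0.08 on slide 2 for the proteins, and 0.32 and 0.46 for the factors. Without the small heat shock proteins, a split chosen after seeing the data, the adjusted p of the protein list was 0.143, and the factors lost their call without array 3 (adjusted p 0.156) and with scaling between arrays (0.0839).

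Known genes of arsenic handling moved in both directions. The phytochelatin synthase PCS1, Os05g0415200, which makes the thiol peptides that bind arsenic, rose by 1.41 ± 0.23, the arsenate reductase HAC1;2, Os04g0249600, by 1.5 ± 0.41, and the vacuolar transporter ABCC1, Os04g0620000, by 1.1 ± 0.40. The reductase ACR2.1, Os10g0545700, rose by 0.38 ± 0.08. Lsi1, Os02g0745100, the silicic acid channel through which arsenite enters, fell to -2.23 ± 0.60, and the efflux carrier Lsi2, Os03g0107300, to -3.11 ± 0.94. HAC1;1, Os02g0102300, at -1.0 ± 0.82, and ACR2.2, Os03g0108000, at 0.17 ± 0.08, did not pass. Nor did the phosphate transporters PHT1;1, Os03g0150600, at -0.02 ± 1.27, PHT1;2, Os03g0150800, at -0.36 ± 0.14, PHT1;4, Os04g0186400, at -0.12 ± 0.80, PHT1;6, Os08g0564000, at 0.55 ± 0.39, and PHT1;8, Os10g0444700, at 0.17 ± 0.76, proteins of the family that takes up arsenate in place of phosphate. PHT1;1 and PHT1;4 had positive values with median centring. As a list of 13 genes, 4 rose and 2 fell (4 and 3 over the list alone), and camera gave an adjusted p of 0.85. Without array 1 none of the 6 genes that passed kept its call in limma, and each kept its sign. ACR2.1 also lost its call with the scanner software's processed signals and with the deposited log2 ratios.

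Glutathione transferases, which join glutathione to foreign compounds, rose as a group. Of 65 tested, 29 rose and 5 fell (32 and 6 over the list alone), led by GST 20, Os10g0530600, at 4.90 ± 0.34 and GSTU31, Os10g0481300, at 4.73 ± 0.33. The camera adjusted p was 0.00796, and 0.984 with an estimated correlation. The list's median was 0.50 on slide 1 and 0.46 on slide 2. In sulfate uptake, cysteine and glutathione synthesis, the supply of the thiols, 13 of 33 rose and 4 fell (13 and 5 over the list alone), with serine acetyltransferase Os03g0196600 at 3.93 ± 0.42 and ATP sulfurylase Os04g0111200 at 3.79 ± 0.13, but the list missed the threshold with an adjusted p of 0.0944. It passed upward with median centring (0.0348), without array 1 (0.0443), without array 2 (0.0177) and with the slide as a block (0.0447). Among thioredoxins, glutaredoxins and peroxiredoxins 17 of 88 rose and 7 fell (14 and 6 over the list alone), with glutaredoxins Os02g0618100 at 5.54 ± 0.30 and Os01g0241400 at 4.54 ± 0.42. Antioxidant enzymes counted 9 higher and 3 lower of 38 in both adjustments, led by peroxiredoxin 6, Os07g0638300, at 3.17 ± 0.28 and glutathione reductase Os10g0415300 at 2.86 ± 0.27. Neither of these 2 lists passed camera, with adjusted p of 0.85 and 0.50, but the antioxidant list passed upward with median centring (0.0232). ABC transporters rose in 23 and fell in 9 of 73 cases (24 and 10 over the list alone, adjusted p 0.13), with PDR-type transporter 2, Os09g0332700, at 3.23 ± 0.28. MATE transporters rose in 5 and fell in 7 of 38 (5 and 6 over the list alone, adjusted p 0.715), with Os10g0345100 at 3.54 ± 0.82 and Os03g0858800 at -3.04 ± 0.68. Of 15 metallothioneins, small metal-binding proteins, 0 rose and 1 fell (0 and 0 over the list alone, adjusted p 0.545), namely MT-1, Os03g0288000, at -0.82 ± 0.39.

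The genes of the iron deficiency response fell together, with the largest median change of the 38 lists. Of 12 tested, 0 rose and 10 fell in both adjustments, with a median log2 ratio of -2.52. They comprised the nicotianamine synthases NAS1, Os03g0307300, at -3.37 ± 1.03, NAS2, Os03g0307200, at -3.59 ± 0.90, and NAS3, Os07g0689600, at -2.67 ± 0.80, the aminotransferase NAAT1, Os02g0306400, at -2.36 ± 0.58, and the deoxymugineic acid synthase DMAS1, Os03g0237100, at -3.58 ± 0.86, all enzymes of the path to mugineic acids, the iron chelators that grass roots secrete. The mugineic acid exporter TOM1, Os11g0134900, fell to -3.23 ± 0.92, the nicotianamine exporter ENA1, Os11g0151500, to -1.59 ± 0.37, the iron chelate importer YSL15, Os02g0650300, to -2.12 ± 0.81, and NRAMP1, Os07g0258400, a metal transporter, to -2.79 ± 0.92. IRO2, Os01g0952800, a transcription factor of the response, fell to -2.20 ± 0.77. The ferrous iron transporters IRT1, Os03g0667500, at -0.88 ± 0.87, and IRT2, Os03g0667300, at -0.91 ± 1.45, did not pass. The camera adjusted p was 6.19e-05, and 0.984 with an estimated correlation. The list's median was -2.89 on slide 1 and -1.75 on slide 2. Without array 1, 9 of the 10 genes no longer passed in limma, all with the same sign. NAS1 and NAS2 are close copies, and signal shared between their probes was not tested.

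Among genes of the phosphate starvation response, 4 rose and 1 fell. The SPX domain genes SPX1, Os06g0603600, SPX2, Os02g0202200, and SPX3, Os10g0392600, which report phosphate status, rose by 1.16 ± 0.17, 1.97 ± 0.28 and 0.74 ± 0.13, and the noncoding RNA IPS1, Os03g0146800, by 1.17 ± 0.19. The phosphate exporter of root vessels PHO1;2, Os02g0809800, fell to -1.63 ± 0.79. PHO2, Os05g0557700, at -0.44 ± 0.68 and the regulator PHR2, Os07g0438800, at 0.17 ± 0.03 did not pass. Over the list of 10 alone the counts were 5 and 2, and the camera adjusted p was 0.31. Without array 1, 4 of these 5 calls were lost in limma.

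**Figure D2:**
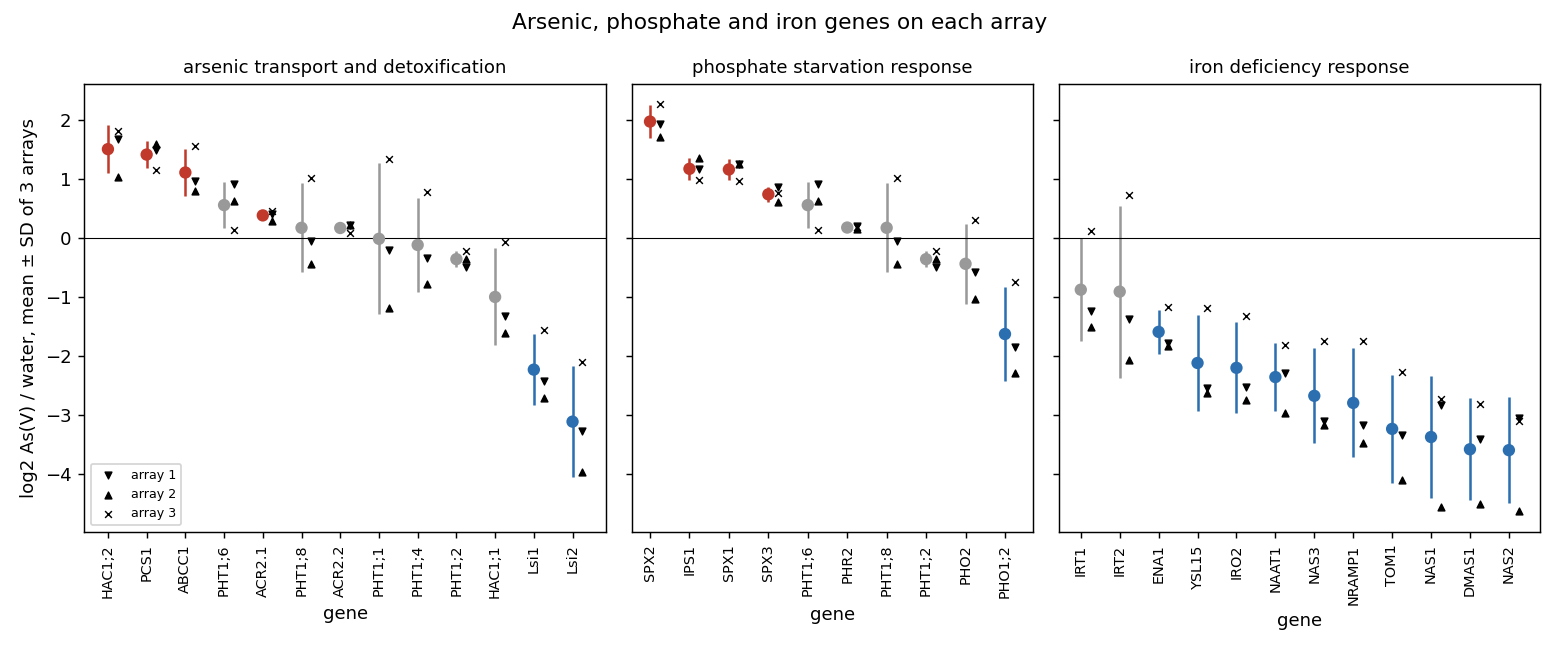
Log2 ratios of As(V) over water of the tested genes of 3 lists, with the mean over 3 arrays as a coloured dot (red higher, blue lower, grey not past the threshold), its SD as a vertical line and the 3 arrays as black symbols beside it. All 10 called iron genes lie below 0 on each array, with array 3 nearest to 0 for 9 of them.

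Genes of the list for jasmonate synthesis and signalling, chosen by description, rose. Of 38 tested, 18 rose and 3 fell (19 and 3 over the list alone), with the reductases Os06g0215500, given above, and Os06g0216300 at 4.89 ± 0.10. Whether these reductases act in jasmonate synthesis was not tested. The list also holds ZIM domain proteins, repressors of jasmonate signalling, of which 7 of 14 rose and 1 fell. The median of the list was 0.41 on slide 1 and 1.05 on slide 2, and camera gave an adjusted p of 0.000889, or 0.984 with an estimated correlation. Genes of abscisic acid response, LEA proteins and dehydrins, a class tied to water deficit, rose in 34 and fell in 12 of 106 cases (35 and 13 over the list alone), with protein phosphatase 2C Os06g0698300 at 4.82 ± 0.26 and the group 3 LEA protein Os05g0542500 at 3.74 ± 0.43. The adjusted p was 0.0197, and 0.984 with an estimated correlation, and medians were 0.23 on slide 1 and 0.29 on slide 2. In trehalose metabolism 5 of 10 rose and 1 fell (6 and 1 over the list alone), with trehalose-6-phosphate phosphatases Os02g0661100 at 2.05 ± 0.29 and Os07g0624600 at 1.57 ± 0.47. Its adjusted p was 0.0437, and 0.984 with an estimated correlation, with medians of 0.65 and 0.95 on slides 1 and 2. Without array 3 the abscisic acid and trehalose lists lost their calls, with adjusted p of 0.0783 and 0.156, as did the first with the stricter filter on dim probes (0.0786) and the second with scaling between arrays (0.0622) or no filter (0.053). For ethylene 21 of 55 rose and 9 fell (22 and 11 over the list alone, adjusted p 0.85), with ACC synthase Os04g0578000 at 3.98 ± 0.41. For auxin 13 of 83 rose and 24 fell (15 and 25 over the list alone, adjusted p 0.112), with the efflux carrier Os09g0554300 at 2.5 ± 0.54 and Os05g0451900 at -2.13 ± 0.75.

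Among regulators, WRKY factors, often linked to defence, rose in 31 and fell in 6 of 64 cases in both adjustments, with WRKY 28, Os06g0649000, at 5.49 ± 0.40 and WRKY 24, Os01g0826400, at 4.10 ± 0.29. AP2/ERF factors rose in 37 and fell in 10 of 87 (42 and 12 over the list alone), with Os02g0546600 at 5.84 ± 0.06. The coactivator Os06g0592500, which the list's pattern also took in, is not described as an AP2 protein. The adjusted p was 0.00945 for WRKY and 0.0437 for AP2/ERF, and 0.984 for both with an estimated correlation. Medians on slides 1 and 2 were 0.26 and 0.72 for WRKY and 0.29 and 0.35 for AP2/ERF, and without array 3 both lost their calls, with adjusted p of 0.0674 and 0.156. AP2/ERF also lost its call with scaling between arrays (0.0955) and with the stricter filter (0.0786). NAC factors rose in 23 and fell in 18 of 66 (26 and 20 over the list alone), with Os01g0816100 at 4.47 ± 0.85 and Os05g0194500 at 4.10 ± 0.36. MYB factors rose in 45 and fell in 34 of 145 (45 and 35 over the list alone), with Os05g0132700 at 5.38 ± 0.24 and MYBS3, Os05g0442400, at 4.62 ± 0.43. In the MAP kinase cascade 11 of 32 rose and 6 fell (12 and 8 over the list alone), with Os07g0584100 at 2.97 ± 0.17 and MAPK5a, Os03g0285800, at 2.03 ± 0.35. Receptor-like kinases rose in 22 and fell in 17 of 85 (23 and 19 over the list alone), with Os08g0374600 at 3.76 ± 0.36 and Os01g0138400 at 3.61 ± 0.13. The camera adjusted p of these 4 lists was 0.85. Calcium signalling genes rose in 57 and fell in 30 of 186 (61 and 32 over the list alone, adjusted p 0.26), with a calmodulin-binding protein, Os11g0506800, at 5.96 ± 0.39 and an EF-hand protein, Os09g0483500, at 4.09 ± 1.07.

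Cell wall proteins, class III peroxidases and cell division genes fell as lists. Cell wall proteins fell in 48 and rose in 26 of 187 cases (55 and 26 over the list alone), with beta-expansin Os03g0102700 lowest and a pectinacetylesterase, Os01g0892500, at 3.02 ± 0.59. Class III peroxidases, secreted enzymes that act on the wall, fell in 35 and rose in 18 of 118 (39 and 19 over the list alone), with Os10g0109600 at -3.22 ± 1.95 and peroxidase 47, Os08g0113000, at -3.11 ± 1.30. Histones, cyclins and DNA replication genes, which mark dividing cells, fell in 36 and rose in 11 of 114 (38 and 11 over the list alone), with cyclin Os04g0552300 at -1.63 ± 0.50 and, upward, histone H2B.2, Os05g0460500, at 1.91 ± 0.43. The adjusted p was 0.0197, 0.0437 and 0.000889 for the 3 lists in turn, and 0.984 for each with an estimated correlation. Their medians were -0.19, -0.29 and -0.20 on slide 1 and -0.14, -0.06 and -0.18 on slide 2. The division genes lost their call with median centring in place of loess, where their median was 0.01 (adjusted p 0.243), and the cell wall list without a filter on dim probes (0.056). The peroxidases lost theirs without array 1 (0.0728), with median centring (0.0659), no filter (0.0597), the stricter filter (0.0698) and the deposited log2 ratios (0.0906).

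The lists that follow did not pass camera, apart from the settings named. Aquaporins fell in 4 and rose in 0 of 19 cases (0 and 0 over the list alone, adjusted p 0.112, and 0.0404 downward without array 3), with Os02g0823100 at -1.80 ± 0.88 and Os07g0448200 at -1.38 ± 0.64. Pathogenesis-related proteins rose in 27 and fell in 15 of 97 in both adjustments (adjusted p 0.938), with chitinase Os10g0543400 at 3.56 ± 0.39 against PBZ1 as the lowest. In phenylpropanoid and lignin synthesis 18 rose and 22 fell of 84 (21 and 22 over the list alone, adjusted p 0.85), with Os04g0447700 at 4.31 ± 1.12 and cinnamoyl-CoA reductase Os08g0277200 at 4.15 ± 0.19. Cytochromes P450 rose in 56 and fell in 46 of 194 (61 and 55 over the list alone, adjusted p 0.767), with Os07g0418500 at 5.30 ± 0.17 and Os01g0627800 at 4.83 ± 1.58. UDP-dependent glycosyltransferases rose in 39 and fell in 34 of 131 (43 and 38 over the list alone, adjusted p 0.99), with Os05g0527000 at 5.32 ± 0.56 and Os02g0755900 at 5.10 ± 1.04. In nitrogen uptake and assimilation 5 rose and 9 fell of 37 (5 and 11 over the list alone, adjusted p 0.651), with nitrate reductase Os02g0770800 at 4.37 ± 0.10 and a nitrate transporter, Os08g0155400, at -2.14 ± 1.02. Fermentation and low-oxygen genes rose in 15 and fell in 8 of 63 in both adjustments (adjusted p 0.715), with hemoglobin 2, Os03g0226200, at 4.64 ± 0.61 and pyruvate decarboxylase Os05g0469600 at 4.28 ± 0.79. Proteasome subunits rose in 8 and fell in 3 of 56 (0 and 0 over the list alone, adjusted p 0.85, and 0.00175 upward with median centring), with Os08g0529100 at 0.90 ± 0.27 and Os07g0614100 at 0.73 ± 0.33. Ribosomal proteins rose in 10 and fell in 14 of 299 (1 and 0 over the list alone, adjusted p 0.306), with L10 proteins Os05g0169100 at 1.46 ± 0.16 and Os12g0105200 at -1.02 ± 0.34. The median of the ribosomal list was -0.02, and 0.37 with median centring in place of loess, where the list passed upward with an adjusted p of 0.00862. It passed downward without array 2, with a median of -0.08 and an adjusted p of 0.011, and with the slide as a block (0.0449). The median, mean and test of 7 lists that did not pass differed in sign, namely arsenic transport, cytochromes P450, MATE transporters, ethylene, NAC, phenylpropanoid and nitrogen. Directional fry, which asks whether the genes of a list move on balance one way and compares them with no other genes, passed 8 of the 12 lists that passed camera and 7 of the other 26. The 4 that did not pass fry were iron deficiency (adjusted p 0.0638), class III peroxidases (0.301), cell wall proteins (0.0679) and trehalose metabolism (0.0514).

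Neither list of markers of other tissues passed camera with all arrays. Photosynthesis genes of green tissue rose in 16 and fell in 10 of 75 cases (16 and 11 over the list alone), with a camera adjusted p of 0.641. The strongest were plastocyanin-like domain proteins, Os08g0482600 at 5.30 ± 0.36 and Os08g0137800 at 4.08 ± 0.32, a family of blue copper proteins that also holds members outside photosynthesis. Seed storage proteins and amylases, which seed remains would bring, rose in 6 and fell in 0 of 16 (7 and 0 over the list alone), with an adjusted p of 0.0944 and medians of 0.59, 0.36 and 0.31 on arrays 1, 2 and 3. Without array 2 this list passed upward, with a median of 0.47 and an adjusted p of 0.0441. A glutelin family protein, Os12g0283400, rose by 4.8 ± 0.38. An alpha-amylase, Os08g0473900, had a fitted log2 ratio of 4.83 ± 0.85 and an adjusted p of 0.0035 on its brightest probe. That probe was not well above background in the water channel on any array, so the size of this value depends on the offset.

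**Figure D3:**
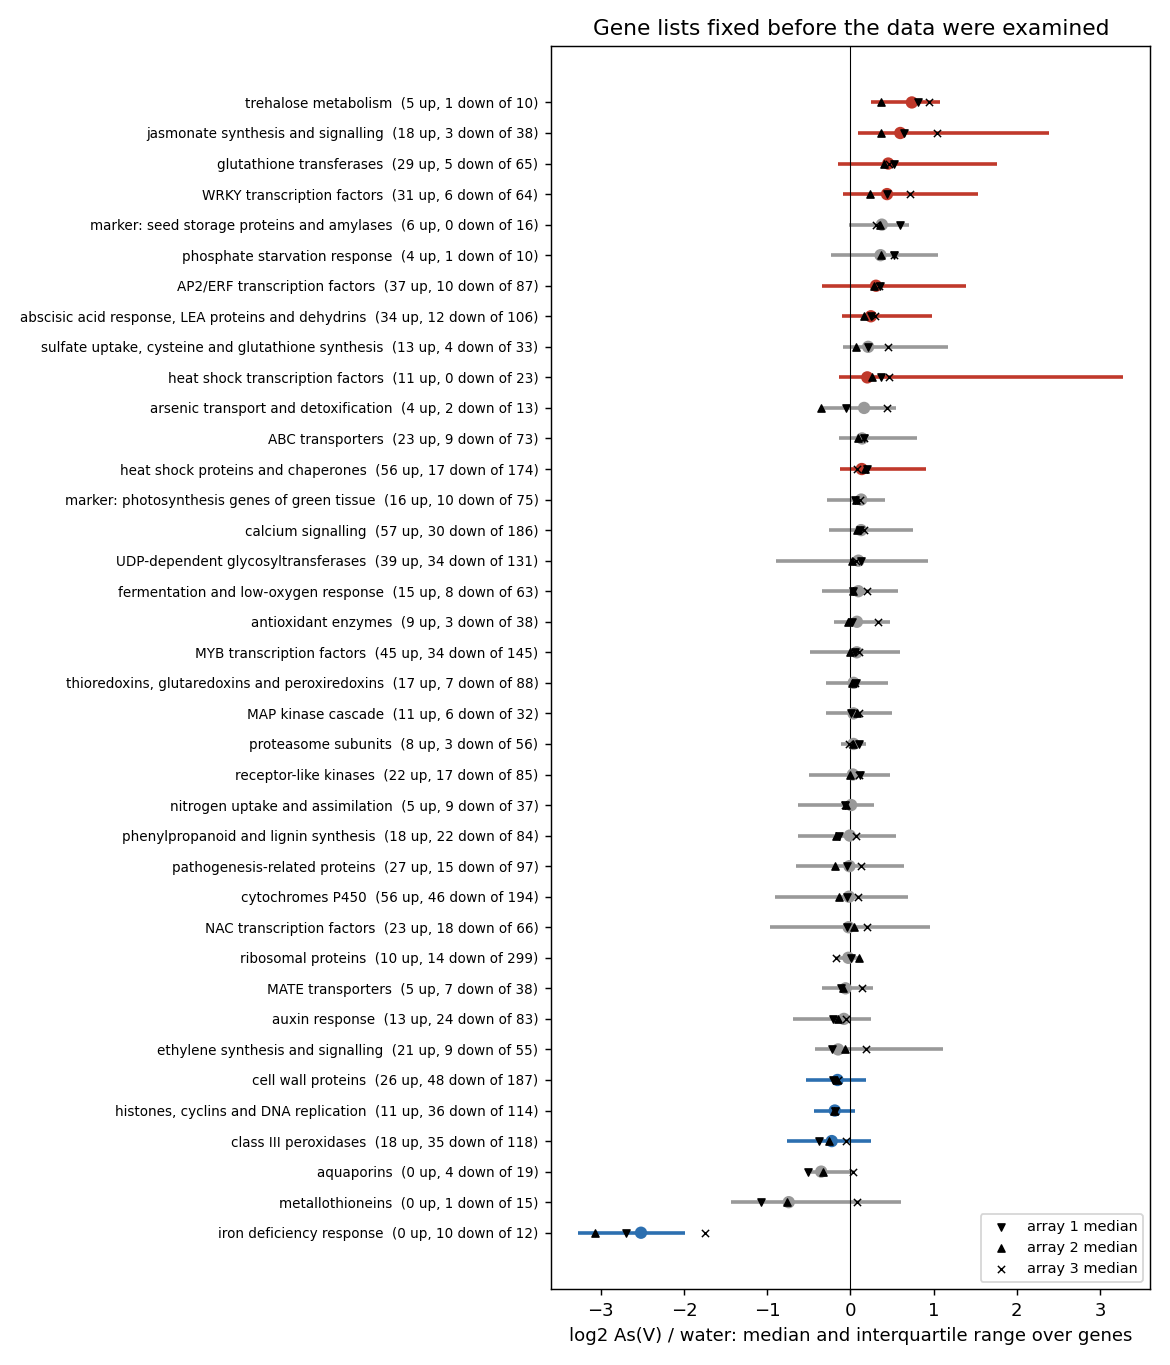
Median log2 ratio of As(V) over water (dot) and interquartile range over genes (line) of each gene list, with the medians of the 3 arrays as black symbols and the counts of genes that rose and fell in the row names. Lists past the camera threshold with the preset correlation are red above and blue below 0, others grey. The iron deficiency list stands apart at -2.52.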

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

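Spots left out of the gene tests because they name no rice gene gave signal above the 153 negative control spots, of which 0.872% were well above background in the As(V) channel. Of 120 spots of random control probes 48.3% were well above background in that channel and 44.7% in the water channel. Of 110 spots of probes for other plant species the shares were 34.5% and 32.7%, of 240 spots of genome probes 27.5% and 25.8%, and of 120 spots of artificial probes 6.11% and 3.89%. Each share is pooled over the 3 arrays. No explanation of these shares was tested.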

How the results depend on the processing

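Among these alternatives, the random slide block and the list without small heat shock proteins were chosen after seeing the data. The random block could not be fitted with 3 arrays on 2 slides, and the separate-channel model was not run for lists. No further pairing was applied, since all arrays form 1 group in which each array already holds a treated and a water sample. Of 7302 higher and 5203 lower probes, 6583 and 4717 kept their call with the scanner software's processed signals and 5633 and 5012 of 5201 tested with the series table, and 0 turned round under any alternative. Of 98 called named genes 94 passed wherever tested under the alternatives that kept all arrays, the test against a 1.5-fold change not being run for single genes, and 44 of the 98 did not pass without array 1. Leaving out 1 array in turn gave 1630 to 9755 probes higher, 147 to 9492 lower, 1630 to 3413 higher and 147 to 3292 lower at least 2-fold, 3 to 10 lists higher and 3 to 5 lower. A test against a 1.5-fold change, stricter by construction, passed 2678 probes higher and 661 lower, and 2652 and 647 at least 2-fold. The series table gave 3190 probes at least 2-fold lower, and the slide block 8856 lower. Lists past the threshold, 8 higher and 4 lower, became 5 higher with scaling between arrays, 2 lower without the filter, 12 higher and 2 lower with median centring, and 0 higher and 0 lower in camera with an estimated correlation (1 list at an unadjusted p under 0.05). The ribosomal list turned upward with median centring, to a median of 0.369. The scanner software's processed signals, median centred here, gave 57.8% of called probes higher and 2472 at least 2-fold lower. The series table, near the same ratios for most probes but not centred, gave 45.9% higher. No further cause was tested for the series table, and none for scaling, filter and centring. All 12 lists passed camera with the slide as a block, the highest adjusted p being 0.0447, in a fit whose residual spread comes from arrays 1 and 2 alone. Signal over background left 5523 of 42418 probes untested.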

Other observations

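The tests of description groups, of other probes and array medians of the iron list, of large rises and falls on each array and among genes bright in the water channel, and of falls against rises on slide 2 were chosen only after the results were seen. The descriptions in the scanner files also group genes outside the fixed lists. Of 254 descriptions shared by at least 8 genes, 5 were lower and 1 was higher at a camera adjusted p under 0.05 with the preset correlation. Sulfotransferase family proteins fell in 13 and rose in 1 of 17 cases, with a median log2 ratio of -1.03 and an adjusted p of 7.6e-05. Members with the NPH3 domain, known from light-directed growth, fell in 7 and rose in 0 of 18 (adjusted p 0.00357), exostosin-like proteins fell in 8 and rose in 0 of 19 (0.00749), the family named after the TGF-beta receptor extracellular region fell in 18 and rose in 4 of 40 (0.00816), and plant disease resistance response proteins fell in 14 and rose in 4 of 27 (0.0241). ZIM domain proteins, repressors of jasmonate signalling that the jasmonate list also holds, rose in 7 and fell in 1 of 14, with a median of 1.53 and an adjusted p of 0.0335. With an estimated correlation the adjusted p was 0.991 for each of the 6.

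The iron deficiency list fell on every array. The 10 further probes of 7 of its genes had a median log2 ratio of -2.53, where a dye bias of single probes would scatter them around 0, and the array nearest to 0 still gave a list median of -1.75. The lowest median among 10000 random lists matched on intensity was -0.92. Genes of a random list were drawn independently, while the estimated correlation within the iron list was 0.868. The comparison thus bears on probe intensity and gives no probability for the list. A biological response to As(V), the treatment the design names, is a hypothesis that stays open together with a dye effect shared by all probes of a gene, which was not tested because the dyes were exchanged on no array.

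Large rises outnumbered large falls 7.93 to 1 among genes that passed the threshold and changed at least 8-fold in the mean of the 3 arrays. With median centring it was 9.91 to 1, which argues against the loess curve as its cause. Among 8993 genes bright enough in the water channel for an 8-fold fall to stay measurable it was 2.19 to 1 (81 rises and 37 falls, bootstrap interval over genes 1.49 to 3.27). Choosing genes on the water signal also leaves out those that rise from a dim start, and all genes together held 460 such large rises and 58 falls. Whether falls were lost in background therefore cannot be told from this ratio and stays open. A count on single arrays, with no threshold on p and so not the same measure, gave other ratios. They ran from 1.47 to 1 on array 2 to 5.38 to 1 on array 1 and 100 to 1 on array 3. Since the arrays of slide 1 differed too, a difference between slides cannot be told apart from one between replicates. A response to As(V) that raises transcripts more than it lowers them was not tested.

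On array 3, falls were weaker relative to rises than on arrays 1 and 2. Of genes chosen on array 1 for an at least 2-fold change, array 3 showed 1.09 times the summed rise of array 2 for 2689 genes, but 0.378 times its summed fall for 2008 genes. The falls' factor over the rises' factor was 0.348 (bootstrap interval over genes 0.334 to 0.361), or 0.444 with arrays 1 and 2 exchanged, which a narrower scale of slide 2 would leave near 1, and at most 0.419 under 3 other ways to process the signals without that exchange. Water RNA mixed into the treated sample of array 3 would need a share of 49.4% from the shallow falls and would then put genes at least 8-fold lower on array 1 at a mean of -0.93, but their mean was -1.88 (SE 0.088, 99 genes), and with arrays 1 and 2 exchanged -1.28 (SE 0.055, 273 genes) against -0.76. The interval and both SE run over genes of single arrays, which are not independent, and do not measure the spread between replicates. The value of 0.444 with arrays 1 and 2 exchanged lay outside that interval. A difference in exposure or material between the replicates stays open as a candidate explanation. So does a difference in slide, scan, scanner or scanner software version, in all of which array 3 differed from arrays 1 and 2. Spike-in signal over background was 18.2, 19.6 and 495 on arrays 1, 2 and 3 in the As(V) channel, and 9.41, 11.3 and 704 in the water channel. The design cannot tell these apart. Apart from the narrower scale, the water RNA and the other ways to process the signals above, none was tested.

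For the probes past the threshold in limma, turning the sign of 1 array at a time gave 4 splits with the real one, too few for a share under 0.05. The real split passed 12505 probes, a number 1 of the 4 splits reached, and the highest of the others passed 0, with at most 638 probes at an unadjusted p under 0.05.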
